A study of Mus musculus with 4 samples.

How the data were processed

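Bulge cells, the stem cell compartment of the hair follicle, were profiled by RNA sequencing in 4 mouse skin samples: 2 from mice in which tamoxifen-inducible Cre under the endothelial Cdh5 promoter deleted Alk1 (Acvrl1), and 2 from littermates without Cre. Per the labels' protocols, all mice received tamoxifen (100 µg per g of body weight) by intraperitoneal injection at postnatal day 17 and were sampled at postnatal day 20. Libraries were directional and polyA-selected, and RNA was taken up in TRIzol. The titles number the mice 1 and 2 in each group. The p-values measure the spread between these samples.

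The deposited values are raw counts per gene, per the labels, for 55536 genes in 4 columns. Per the submitters' processing notes, reads were handled with Trim Galore 0.6.0, cutadapt, FastQC and STAR 2.7.0e against GRCm38 (mm10), and DESeq2 1.26.0 was used. The counting tool, its strand setting and the annotation release are not given in the sources used here. Genes in near-identical families, and antisense or overlapping genes, are therefore uncertain. All 55536 identifiers matched GENCODE M21 gene models on GRCm38, from which symbols, coordinates, exon lengths and GC content were taken.

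The counts were analysed with R 4.3.3. Genes were kept by edgeR 4.0.16's filterByExpr, which left 14259 genes. After TMM normalization, knockout and control libraries were compared with edgeR's quasi-likelihood test (robust fit, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression is given as CPM (counts scaled to effective library size) with the SD over 2 libraries. Log2 CPM used a prior count of 2. Gene lists (48, fixed before the data were examined) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested genes, leaving 44 lists. Camera with an estimated correlation and fry stood beside it. Members were also adjusted over their own list alone, which does not correct for the choice among the 44 lists. The lists of lymphatic endothelium, skeletal muscle and mast cells or neutrophils had too few tested genes, and sex-linked genes served only as a check.

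The named genes followed a rule fixed before the data were examined. Acvrl1, Bmp4, Mki67, Cd34 and Lgr5 were always named. Of genes past the threshold, up to 10 per direction of largest change were to be named, with a mean of at least 2 CPM, no overlap of groups, and no predicted gene, Rik, pseudogene or sex-linked symbol. If none passed, the 5 of smallest p per direction were named. From each described list, up to 4 members past the threshold were named, or, if none passed, the 2 of highest mean CPM. Other genes named were chosen after their values were seen. The values of 1 list member are not reported here.

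Depth ran from 16326906 to 29130974 counts per library. On simulated counts drawn from the 14259 genes' means, dispersions and library sizes, with 50 genes changed at each fold, the edgeR test recovered 8% of 1.5-fold, 64% of 2-fold, 92% of 4-fold and 100% of 8-fold changes. It made 155 calls, of which 23 were false. The changed genes were drawn from those with a mean of at least 2 CPM, and the counts held no variation beyond these dispersions. In the data, Gpnmb at 5.52-fold did not pass (edgeR adjusted p = 0.080), so these shares may overstate recovery. A simulated list of 40 genes shifted by 0.5 (log2) was detected by camera with an estimated correlation (unadjusted p = 0.012), and an unshifted one was not (p = 0.999). Genes were simulated independently of each other. The real ribosomal protein, G2/M and cholesterol lists had estimated correlations of 0.34, 0.52 and 0.72. The simulation therefore does not show that such a shift could be detected in correlated lists. Replicates were not duplicates: the chi-square per degree of freedom was 31.6 between controls and 41.9 between knockouts.

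Alternatives fixed beforehand were RLE and upper-quartile normalization, no filter, a filter of at least 50 counts in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a log2 fold threshold of 1, estimated correlation and fry. Removal of a trend on exon length and GC content (splines with 4 degrees of freedom) was added after seeing the data. With 2 libraries per group, a single outlying library within a group could not be tested for.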

Results

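RNA was sequenced from bulge cells of mouse skin at postnatal day 20, 3 days after tamoxifen. Deletion of Alk1, the receptor encoded by Acvrl1, was driven in endothelium. The question was how loss of endothelial Alk1 changes transcripts of hair follicle stem cells around their activation. Control replicates 1 and 2 held 16326906 and 29130974 counts, and knockout replicates 1 and 2 held 22261317 and 21237843. Of 24037 genes with a count, 14259 were tested, with a biological coefficient of variation of 19.2%.

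The targeted gene Acvrl1 (chromosome 15, 101128522 to 101145336, GRCm38) measured 23.0 ± 1.9 CPM in controls and 20.5 ± 3.7 CPM in knockouts (SD, n = 2 each), a log2 fold change of -0.16 ± 0.19 (SE; edgeR adjusted p = 0.76). Deletion was directed at endothelium and counts cover the whole gene, so this value does not check the labels. Bmp4, a secreted signal named in the study's title, measured 2.48 ± 0.97 and 2.02 ± 0.32 CPM (log2 fold change -0.28 ± 0.41, adjusted p = 0.82). Its sign turned when control 1 was left out (0.17). Cd34, a bulge surface marker, gave -0.17 ± 0.19 (adjusted p = 0.75), and Lgr5, a receptor of follicle stem cells, -0.13 ± 0.16 (adjusted p = 0.77). Mki67, a proliferation marker, measured 8.91 ± 1.96 CPM in controls and 4.29 ± 0.24 in knockouts. Its log2 fold change was -1.05 ± 0.27, with an edgeR adjusted p of 0.43. None of these 5 genes passed the threshold, and Mki67 passed only in the edgeR fit without a count filter (-1.05, adjusted p = 0.047). In that fit the spread pooled over genes outweighed each gene's own spread.

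One transcript passed. Rps26-ps1, a transcribed processed pseudogene of the ribosomal protein gene Rps26 (ENSMUSG00000059775, chromosome 8, 107439131 to 107439579, GRCm38), was 1.28 ± 0.29 CPM in controls and 63.0 ± 0.006 CPM in knockouts. The log2 fold change was 5.57 ± 0.20 (edgeR adjusted p = 0.0015). It was named after its values were seen, and pseudogene counts can take reads from near-identical copies. Its counts were 0.198% and 0.287% of those of Rps26 in controls and 11.5% and 12.2% in knockouts.

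No gene passed as lower in the main edgeR test. At an unadjusted p under 0.05, 685 genes were higher and 847 lower, where 713 in all are given by chance. Both knockout libraries lay above both controls for 21.3% of genes and below both for 23.6%, against 16.7% each by chance. DESeq2 called 22 genes higher and 58 lower of 13624, and without a count filter edgeR called 163 and 267. In that unfiltered fit the prior degrees of freedom, the weight of the spread pooled over genes, were infinite, against 4.17 in the main fit. A gene's own spread therefore hardly counted there. With the replicate number as a block, which the labels do not give as a pairing, edgeR called 106 genes. The prior degrees of freedom of the block fit were 22.6, so pooled spread weighed more there than in the main fit. The median exon length was 9078.5 bases for the genes DESeq2 called lower and 3862.5 for those called higher, against 4180 for tested genes. With an unadjusted edgeR p under 0.01, 105 of the 220 lower genes were in the longest decile. Leaving out knockout 1 gave 39 and 26, leaving out knockout 2 gave 2 and 2, and leaving out control 1 gave 2 and 0.

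The 5 genes of smallest p in each direction did not pass the threshold in the main edgeR test. All 10 passed with DESeq2, with edgeR without a count filter and with edgeR with the replicate number as a block. These refits use the same libraries and are not independent of each other. Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes, measured 15.2 ± 0.7 CPM in controls and 83.6 ± 20.9 CPM in knockouts (log2 fold change 2.47 ± 0.20, adjusted p = 0.080). Fxyd6, a regulator of the sodium pump, gave 1.09 ± 0.14, and Hspa8, a constitutive chaperone, 0.90 ± 0.12. Pnp, a purine salvage enzyme, gave 1.18 ± 0.16, and the secreted protease Htra1 0.75 ± 0.12. On the lower side, Il31ra, a subunit of the interleukin 31 receptor, measured 505 ± 32 CPM and 181 ± 6 CPM (log2 fold change -1.48 ± 0.12, adjusted p = 0.080). Sorl1, a sorting receptor, gave -1.28 ± 0.15, Lmo7 -0.80 ± 0.11, the ubiquitin ligase Cblb -0.88 ± 0.12 and Stard4, a sterol carrier, -1.18 ± 0.17. For the 8 genes other than Gpnmb and Il31ra, adjusted p was 0.36 or 0.43. Gpnmb passed with edgeR when the length and GC trend was removed (adjusted p = 0.019) and without knockout 2 (0.0087). Without knockout 1, Gpnmb (0.0021), Fxyd6 (0.024), Il31ra (0.024), Sorl1 (0.041) and Stard4 (0.040) passed.

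**Figure D1:**
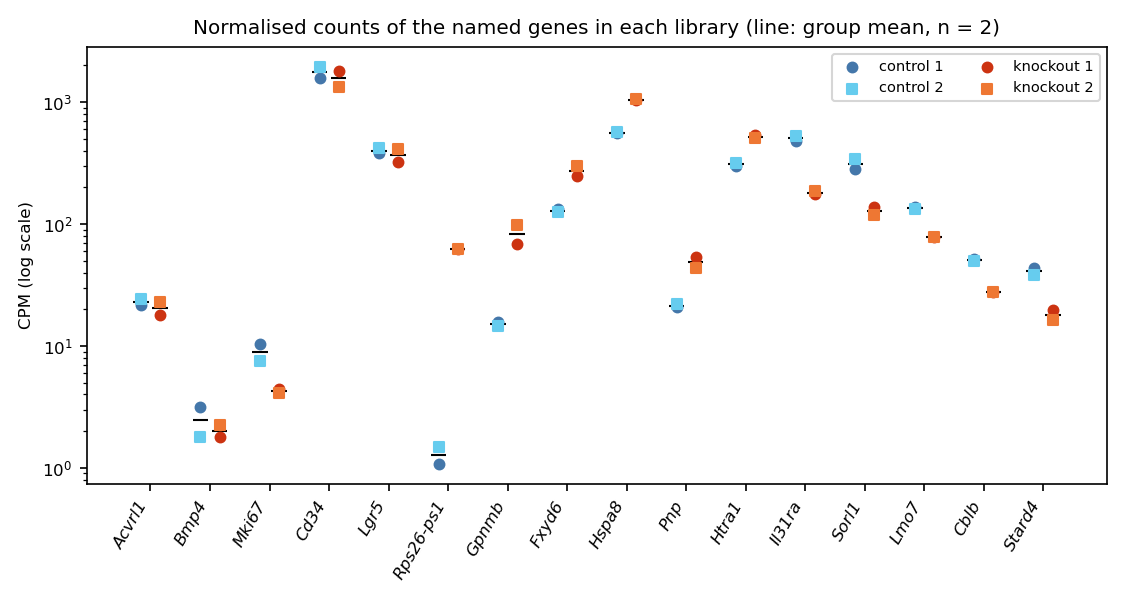
CPM (log axis) of the named genes in each of the 4 libraries; circles are replicate 1, squares replicate 2, and lines group means (n = 2). Rps26-ps1 lies near 63.0 CPM in both knockouts and under 1.5 in both controls, and Gpnmb is at 68.9 and 98.4 CPM in knockouts.

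Of 44 gene lists, camera called 7 higher and 6 lower. None was called with an estimated correlation, where every called list had an adjusted p = 0.86 with an estimated correlation, and none by fry, whose smallest adjusted p was 0.61. The list shifts came with a trend on transcript length. Across genes, which are not independent replicates, the Spearman correlation of log2 fold change with exon length was -0.25, and deciles ran from a median of 0.12 (shortest) to -0.19 (longest).

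**Figure D2:**
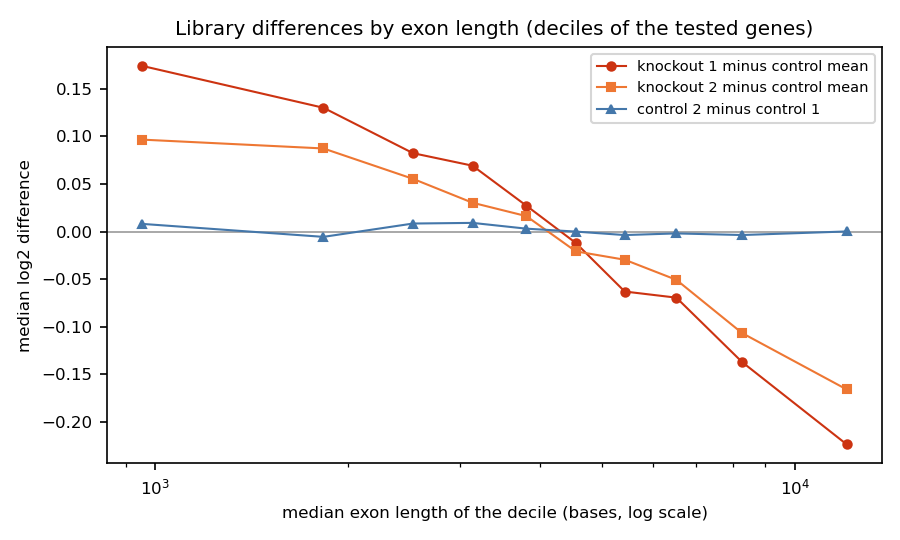
Median log2 difference (y axis) against median exon length of each decile of tested genes (bases, log x axis), for each knockout minus the control mean and for control 2 minus control 1. Both knockouts fall with length, from 0.17 and 0.10 to -0.22 and -0.17, while the control pair stays between -0.006 and 0.009.

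Cell cycle lists were lower. Of 42 G2/M genes, 39 had a log2 fold change below 0, with a median of -0.79 (camera adjusted p = 2.5e-10; adjusted p = 0.86 with an estimated correlation). In the main edgeR test no member passed over all genes or adjusted over the list alone. The members of highest expression, Ncapd2, a condensin subunit, and Hmgb2, a chromatin protein, gave -0.52 ± 0.17 and 0.28 ± 0.15. Library medians were 0.27 and -0.27 in controls and -0.54 and -0.96 in knockouts, lower in number 2 within each group. Markers of other cell types were ordered the same way within groups: sebaceous gland genes at 0.67, -0.67, -0.07 and -0.96 and interfollicular differentiation genes at 0.81, -0.81, 0.19 and -0.65. Without control 1 the G2/M median was -0.42, and the list was called in each of the 12 refits. The G1/S list had 26 of 37 genes below 0 and a median of -0.25 (adjusted p = 0.032; adjusted p = 0.86 with an estimated correlation). Pcna and Mcm6, replication factors, gave 0.15 ± 0.13 and 0.31 ± 0.14, against the list's direction. Its call was lost without control 1 (median -0.20, adjusted p = 0.10), without knockout 2 (-0.11, 0.33) and with the stricter filter (-0.22, 0.060).

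**Figure D3:**
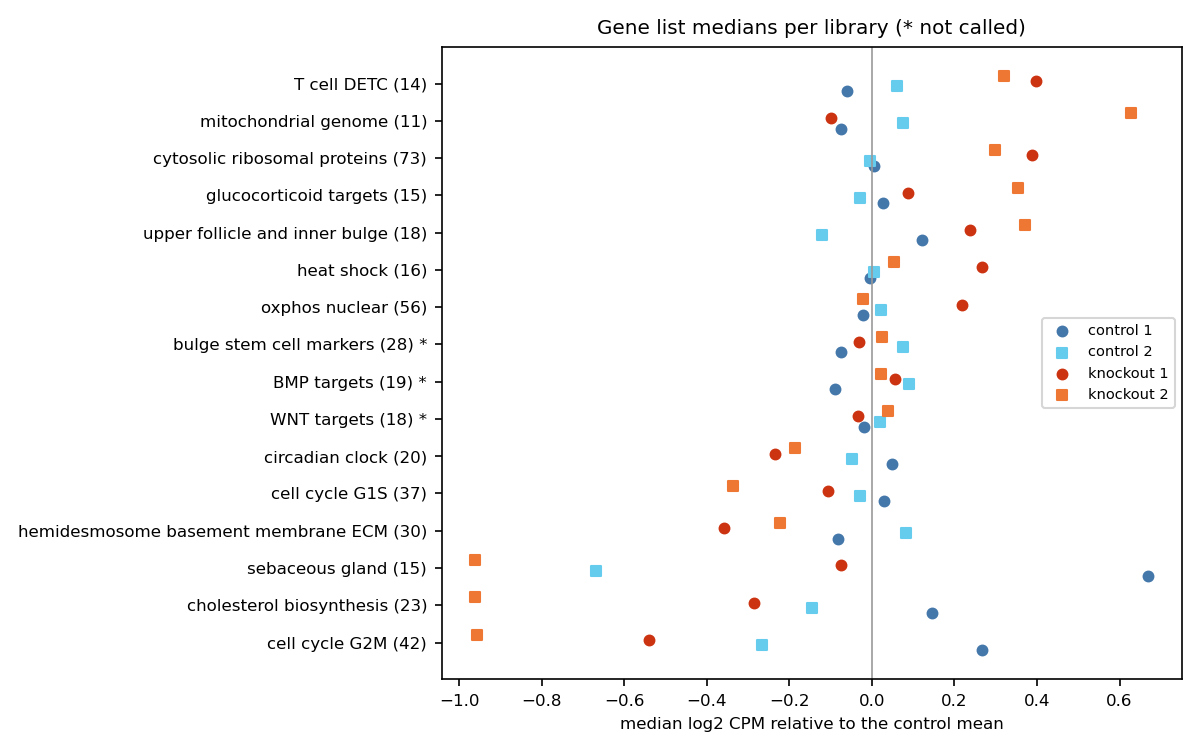
Median over list members of log2 CPM relative to the control mean (x axis), per library, for the called lists and 3 uncalled primary lists (asterisk); tested members are in brackets. G2/M medians were 0.27, -0.27, -0.54 and -0.96 in controls 1 and 2 and knockouts 1 and 2.

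Cholesterol synthesis genes were lower. All 23 tested members had a log2 fold change below 0, with a median of -0.67 (camera adjusted p = 7.3e-12; adjusted p = 0.86 with an estimated correlation). In the main edgeR test none passed over all genes, while DESeq2 called 2 lower, among them Stard4 (adjusted p = 0.00020). With edgeR, 5 passed adjusted over the list alone, among them Stard4, Lss (-0.71 ± 0.13), Srebf2 (-0.47 ± 0.11) and Fdft1 (-0.87 ± 0.21). Lss and Fdft1 were named after their values were seen. Srebf2 is the transcription factor of this pathway, and Hmgcs1, an early enzyme, gave -0.20 ± 0.22. Library medians were 0.15 and -0.15 in controls and -0.29 and -0.96 in knockouts, in the same order within groups as those of sebaceous gland and interfollicular differentiation genes. The median of the cholesterol list was -0.30 without control 1, -0.37 without knockout 2 and -1.05 without knockout 1.

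Ribosomal protein genes were higher, with 70 of 73 above 0 and a median of 0.33 (camera adjusted p = 8.8e-21; adjusted p = 0.86 with an estimated correlation). Rps14 gave 0.49 ± 0.13 and Rplp0 0.29 ± 0.13. These genes have a median exon length of 1830 bases, against 4180 for tested genes, and with the length and GC trend removed their median was 0.32 (adjusted p = 1.9e-14). Genes of the respiratory chain encoded in the nucleus had a median of 0.11 (46 of 56 above 0, adjusted p = 0.0032). Atp5a1 and Atp5b, subunits of ATP synthase, gave 0.08 ± 0.14 and 0.03 ± 0.14. The median was -0.026 without knockout 1 (adjusted p = 0.98) and 0.22 without knockout 2. Mitochondrially encoded genes had a median of 0.34 (11 of 11 above 0, adjusted p = 0.033), with mt-Nd1 at 0.34 ± 0.19 and mt-Co1 at 0.31 ± 0.26. Without knockout 2 the median was -0.10 (adjusted p = 0.78), and without knockout 1 it was 0.63. Both lists had adjusted p = 0.86 with an estimated correlation. Their calls also ended without control 1 (medians 0.078 and 0.28, adjusted p = 0.086 and 0.12) and with the length and GC trend removed (medians 0.096 and 0.29, adjusted p = 0.13 and 0.31). Camera compares a list with the other genes, and the median of all tested genes moved from -0.021 to 0.043 with that removal. The mitochondrially encoded list also lost its call with the stricter filter (median 0.31, adjusted p = 0.088) and with voom (0.31, 0.052).

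The list of hemidesmosome, basement membrane and matrix genes had a median of -0.28 (26 of 30 below 0, camera adjusted p = 1.6e-06; adjusted p = 0.86 with an estimated correlation). One member, Frem2 (-1.19 ± 0.21), passed adjusted over the list alone, and was named after its values were seen. Postn and Col17a1 gave -0.25 ± 0.21 and -0.07 ± 0.13. The list's median exon length was 8006 bases, and with the length and GC trend removed its median was -0.12 (camera adjusted p = 0.0044). The circadian clock list had a median of -0.18 (14 of 20 below 0, adjusted p = 0.0042; adjusted p = 0.86 with an estimated correlation), and 4 members passed adjusted over the list alone: Tef (-0.68 ± 0.12), Dbp (-0.99 ± 0.18), Per2 (-1.77 ± 0.33) and Bhlhe41 (-0.86 ± 0.23). Dbp, Per2 and Bhlhe41 were named after their values were seen. Over all genes, 3 members passed with DESeq2: Per2 (adjusted p = 0.0040), Tef (0.0087) and Dbp (0.012). Tef also passed with edgeR without a count filter (0.0015). Per1, a core clock gene, gave -0.18 ± 0.17. With the length and GC trend removed the circadian list was still called (camera adjusted p = 0.012). The call was lost without knockout 1 (adjusted p = 0.12), and the median was -0.04 with the length and GC trend removed.

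Heat shock genes had a median of 0.17 (11 of 16 above 0, adjusted p = 0.032), of which Hspa8 passed adjusted over the list alone and Hsp90ab1 gave 0.22 ± 0.12. The median was 0.049 without knockout 1 (adjusted p = 0.89) and 0.27 without knockout 2. Glucocorticoid targets had a median of 0.31 (11 of 15 above 0, adjusted p = 0.033), with Cebpd (0.76 ± 0.14, named after its values were seen) passing adjusted over the list alone. Tsc22d3 and Sgk1 gave 0.40 ± 0.12 and 0.37 ± 0.26. The median was 0.014 without knockout 2 (adjusted p = 0.86) and 0.16 without control 2 (adjusted p = 0.21). Upper follicle and inner bulge keratinocyte genes had a median of 0.25 (14 of 18 above 0, adjusted p = 0.0036), with Krt17 at 0.59 ± 0.14 and Krt6a at 0.44 ± 0.25. Krt17 passed over all genes with edgeR without a count filter (adjusted p = 0.018). The 3 lists had adjusted p = 0.86 with an estimated correlation. The median of the upper follicle list was 0.45 without control 1. The heat shock call was also lost without control 1 (median 0.17, adjusted p = 0.14) and with the length and GC trend removed (0.18, 0.065), and the glucocorticoid call with voom (0.33, 0.051) and the length and GC trend removed (0.28, 0.085).

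Sebaceous gland genes had a median of -0.44 (13 of 15 below 0, adjusted p = 0.032; adjusted p = 0.86 with an estimated correlation), with Dgat2 at -0.40 ± 0.39 and Plin2 at -0.16 ± 0.16. The call was lost without control 1 (median 0.24, adjusted p = 0.74) and without knockout 2 (-0.20, 0.55). The median was -0.86 without control 2 and -1.09 without knockout 1, and the call was also lost with voom (adjusted p = 0.14). T cell genes had a median of 0.35 (11 of 14 above 0, adjusted p = 0.032; adjusted p = 0.86 with an estimated correlation). Thy1 and Trbc2 gave -0.04 ± 0.37 and 0.02 ± 0.22. That call was lost without control 1 (median 0.30, adjusted p = 0.071), without knockout 1 (0.38, 0.41), with the stricter filter (0.26, 0.11), with voom (0.32, 0.052) and with the length and GC trend removed (0.33, 0.13). Without control 2 its median was 0.58.

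Bulge stem cell markers had a median of 0.04 over 28 genes (camera adjusted p = 0.49). Krt15 gave 0.16 ± 0.13 and Krt5 0.02 ± 0.16. The list was called higher without control 2 (median 0.10, adjusted p = 0.027). BMP targets had a median of -0.04 over 19 genes (adjusted p = 0.75), with Id2 at 0.26 ± 0.15 and Id4 at 0.21 ± 0.12. WNT targets had a median of -0.11 over 18 genes (adjusted p = 0.90), with Lgr6 at -0.25 ± 0.17. The mean log2 fold change of the BMP and WNT lists was 0.003 and 0.05, and camera's direction was up, so median and test differed in sign. No member of these 3 lists passed adjusted over the list alone.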

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

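All tests of explanations in this part were chosen after the results were seen and revised, with tests replaced, after a first run; for the search near Cdh5 only the values themselves were unseen. Counts of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty), which were not tested, reached 24 in knockout 1 against 0 and 1 in controls and 0 in knockout 2. Xist was present in each library, at 387 and 400 CPM in controls and 192 and 216 CPM in knockouts. It was lower with DESeq2 (adjusted p = 3.1e-05) but not in the main edgeR test (0.36). Its exon length, 17946 bases, puts it in the longest decile, which was lower in knockouts as a whole. The log2 fold change of Xist, -0.95 ± 0.13, was well below that decile's median of -0.19.

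Rps26-ps1 was high in both knockouts and low in both controls. Reads moved from Rps26 would lower Rps26 by 61.7 CPM, but it differed by 0.46 CPM (SE 21.6), which argues only weakly, at 2 libraries per group, against a move of that size. Without Rps26-ps1, 6 of 62 processed pseudogenes at 5 CPM or more in a library switched at least 16-fold between libraries. The odds ratio was 116 (Fisher's exact test, two-sided). All 6 also differed within a group, by a looser cut than 16-fold: Gm14165 measured 4.91 and 0.64 CPM in controls and 10.5 and 9.34 CPM in knockouts. The 5 CPM floor left out AC115117.1 (2.57 and 2.51 CPM in controls, 0.092 and 0.048 in knockouts). It also left out Gm14292 (1.32 and 3.18 CPM in controls, 0.092 and 0.14 in knockouts). Both are processed pseudogenes that part the groups, so the finding that all 6 differ within a group depends on the floor. The excess cannot single out inherited sequence differences, because no sequence variant was examined and misplaced reads of near-identical copies could also give it. Such differences remain a candidate for the Rps26-ps1 counts. The gene lies 3.29 Mb from Cdh5, whose promoter drives Cre in knockouts, and of 166 other tested genes within 10 Mb, 0 had an unadjusted p under 0.01 (odds ratio 0, upper 95% bound 0.989, Fisher's exact two-sided p = 0.055), which argues marginally against a broad change there. One of these 166 genes, the processed pseudogene Gm8730 (102864845 to 102865798), measured 63.5 and 2.00 CPM in controls 1 and 2. It measured 126 and 103 CPM in knockouts, so it switched within controls and the count at this p bound does not show it. A difference at single pseudogenes such as Rps26-ps1, linked or a response to Alk1 loss, was not tested and stays open. Where the Cre transgene sits is not given in the sources used here.

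The gene list shifts came with a length trend. The Spearman correlation of log2 fold change with exon length was below 0 in each quartile of expression (-0.15 at its weakest, -0.47 at its strongest), so the trend was not confined to 1 level of expression. Within groups it was -0.005 and 0.08, and RNA integrity or fragment length cannot be told apart from a change in the cells that follows transcript length, because the trend goes with the groups. For the G2/M list, the trend as the whole cause is argued against by its median, which was -0.71 after removal of the trend and -0.79 before. Its median exon length, 4926.5 bases, is near the 4180 of tested genes, so removal could move it little. The ribosomal protein list, of shorter genes (1830 bases), moved from 0.33 to 0.32. The hemidesmosome and circadian medians moved from -0.28 to -0.12 and from -0.18 to -0.04. Both lists were still called (camera adjusted p = 0.0044 and 0.012). The median of all tested genes itself rose from -0.021 to 0.043 with the removal. List medians after removal include that rise, which brings lower lists nearer 0 and holds up higher ones. In all, 8 of the 13 called lists were still called, of the higher ones only the ribosomal protein and upper follicle lists.

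The split of libraries numbered 1 against 2 called 87 genes, all higher in number 1, against 1 for knockout against control and 0 for the remaining split, which points to a structure of the samples. Of the 87 genes, 12 belong to the 25 tested interfollicular differentiation genes, including Krt1, Krt10 and Lor (0.15 expected), so more differentiated epidermal cells in the libraries numbered 1 may contribute. Lower depth is argued against, since knockout 1 had 1.05 times the counts of knockout 2. With 3 splits of 4 libraries, of which 2, the real one included, called at least as many genes as the real one, the share cannot fall under 0.05; the real value was 1 and the highest other 87. The design names no group for this split, so no biological cause of the cell mix was tested.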

How the results depend on the processing

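The length and GC trend removal was chosen after seeing the data. Rps26-ps1 passed in each of the 12 refits (log2 fold change 5.40 to 5.88). Counts of genes higher and lower were 1 and 0 with RLE, upper quartile, the stricter filter, voom and the fold threshold. They were 163 and 267 with no filter, 22 and 58 with DESeq2, 2 and 0 with the trend removed, and 24 and 40 with the trend removed and the block. The labels give the mice a number and no pairing: with 2 pairs, the correlation of replicate 1 minus 2 between the groups was 0.12 (Pearson) and 0.00012 (Spearman), and the replicate block moved the counts to 25 and 81. With it the 10 genes of smallest p all passed, and the heat shock (median 0.17, adjusted p = 0.056) and glucocorticoid (0.32, 0.061) lists were not called. Lists called higher were 4 with voom and 2 with the trend removed, and 0 higher and 0 lower with an estimated correlation or fry, where the G1/S (-0.25) and G2/M (-0.79) calls were lost. The G1/S median was -0.22, not called, with the stricter filter. The BMP target median was 0.030 with voom and 0.015 with the trend removed, and the WNT target median 0.0088. With the trend removed, Lgr5 was 0.053, Col17a1 0.037 and Trbc2 -0.039. The median of all tested genes rose from -0.021 to 0.043 with that removal. The turns above 0 of both list medians, Lgr5 and Col17a1 with the trend removed include this rise, while Trbc2 turned the other way.

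Leaving out each library, where the lone library is assumed to vary like the other group's, gave these ranges. Genes higher ran from 1 to 39 and lower from 0 to 26, both highest without knockout 1. Lists lower ran from 6 to 11 (highest without control 2). Medians ran from -0.36 to -0.11 for G1/S, -1.09 to 0.24 for sebaceous, -0.032 to 0.10 for bulge markers, -0.19 to 0.14 for BMP targets, -0.10 to 0.035 for WNT targets, -0.026 to 0.22 for nuclear respiratory and -0.10 to 0.63 for mitochondrial genes. Log2 fold changes ran from -0.63 to 0.17 for Bmp4, -0.44 to 0.078 for Hmgcs1, -0.83 to 0.25 for Dgat2, -0.31 to 0.036 for Plin2, -0.15 to 0.17 for Krt5, -0.41 to 0.032 for Cd34, -0.53 to 0.10 for Postn, -0.13 to 0.019 for Col17a1, -0.69 to 0.40 for Thy1, -0.17 to 0.18 for Trbc2, -0.36 to 0.0064 for Acvrl1, -0.31 to 0.035 for Lgr5, -0.059 to 0.20 for Atp5a1, -0.12 to 0.17 for Atp5b, -0.40 to 0.019 for Per1, -0.011 to 0.78 for Krt6a, -0.14 to 0.65 for mt-Co1 and -0.044 to 0.68 for Sgk1. Without a turn of sign, they ran from 0.028 to 0.25 for Pcna, 0.16 to 0.45 for Mcm6, 0.12 to 0.43 for Hmgb2, 0.059 to 0.57 for mt-Nd1, 0.042 to 0.31 for Krt15, 0.11 to 0.46 for Id2 and -0.43 to -0.085 for Lgr6. The cause was not tested.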

Other observations

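The tests of lysosomal genes and of chromosome 18 were chosen after the results were seen, and the other lists of this part were fixed beforehand.

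Other cell types and programmes, none of which passed camera's threshold, had these median log2 fold changes. Fatty acid synthesis genes gave -0.29 (adjusted p = 0.064), and 4 of 15 passed adjusted over the list alone: Fasn (-0.67 ± 0.15), Acaca (-0.51 ± 0.12) and Scd2 (-0.70 ± 0.19) were lower and Fads1 (1.48 ± 0.40) higher. Notch1 (-0.48 ± 0.11) and Notch2 (-0.64 ± 0.15) passed adjusted over the notch list alone, whose median was -0.14. Col1a1 and Col5a1 (-0.69 ± 0.16 and -0.91 ± 0.18) passed within the dermal fibroblast list (median -0.11). In the melanocyte list (median -0.06) Gpnmb and Mitf (-0.60 ± 0.12) passed, in opposite directions, and Cck (-2.05 ± 0.45) passed within the Merkel cell list (-0.34). These genes were named after their values were seen.

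Blood endothelial genes gave -0.25, with library medians of 0.19 and -0.19 in controls and -0.58 and 0.32 in knockouts. Interferon genes gave 0.25, with 0.63 in knockout 2 and -0.20 in knockout 1. Interfollicular differentiation genes gave -0.43, with 0.81 and -0.81 in controls and 0.19 and -0.65 in knockouts. Red blood cell genes gave 0.76 over 5 genes, with -0.28 and 0.28 in controls and 1.01 and -0.06 in knockouts, and dermal papilla genes gave 0.57 over 6. The remaining medians were 0.18 for Langerhans and dendritic cells, 0.21 for macrophages, -0.17 for hedgehog targets, -0.06 for cytokines, 0.11 for immediate early genes, -0.25 for pericytes, -0.06 for Schwann cells, -0.03 for TGFβ targets, -0.004 for hypoxia, 0.001 for WNT components, -0.29 for the hair matrix and shaft, -0.05 for Runx1 and activation genes, -0.05 for cell cycle inhibitors, -0.002 for p53 targets, 0.02 for hair germ markers, -0.03 for the unfolded protein response, 0.04 for adipocytes and -0.13 for BMP components. Camera adjusted p ran from 0.060 to 0.989 over these lists.

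A hypothesis from Gpnmb and Ctsl (1.24 ± 0.23), both lysosomal, was that lysosomal genes rose as a group. Without Ctsl, Acp5 and Atp6v0d1, which had been looked at singly, 56 genes had a median of 0.13, 38 of them above 0. Camera gave p = 0.0039, and 0.22 with an estimated correlation, so a small shared rise rests on the preset correlation. Members also fell, among them Naglu (-0.67 ± 0.18), Mitf (-0.60 ± 0.12) and Atp6v0a1 (-0.52 ± 0.13). A median of 0.13 is well below Gpnmb (2.47 ± 0.20) and Ctsl, so a rise of that size would account for little of theirs. The test was first written on the full list, whose 59 genes had a median of 0.15 (camera p = 0.00025, and 0.16 with an estimated correlation). None of the 59 passed in the main edgeR test. Ctsl passed with DESeq2 (adjusted p = 0.00014) and with edgeR without a count filter.

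Stard4 and 2 neighbours on chromosome 18, AC115117.1 (-5.07 ± 0.56) and Nrep (-1.51 ± 0.25), lie within 265 kb (33199355 to 33464029, GRCm38). AC115117.1 is a processed pseudogene of low counts, at 2.57 and 2.51 CPM in controls and 0.092 and 0.048 CPM in knockouts. Processed pseudogenes also switched between libraries elsewhere in these data. All 3 genes passed as lower with DESeq2 but not in the main edgeR test. Stard4 and Nrep also passed with edgeR without a count filter, and Stard4 and AC115117.1 with the replicate block. A change spread over 1 Mb on either side is argued against by the 13 other tested genes there, with a median of 0.063 and 5 below 0. All 13 lie outside the 265 kb, so a change confined to these 3 genes stays open.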
